A study of Mus musculus with 16 samples.

How the data were processed

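The data were poly(A)-selected RNA of mouse ESCs in 4 groups of 4 libraries. The authors ran kallisto on GRCm38 transcripts and deposited 1 table of transcript abundances per library, 16 in all. Per the file headers the deposited values are estimated counts (expected counts), TPM and effective lengths, and estimated counts were used for the tests. Effective lengths entered only the length-scaled TPM counts, an alternative named below. The kallisto version was not given in the sources used here. Labels state 800000 cells per sample, RNA purified with RNeasy columns, 1 µg of RNA as input and poly(A) selection with a NEBNext module. Transcript identifiers were matched to GENCODE M21, where 116728 of 118489 were found. The 1761 others held 0.656% to 0.712% of the counts of a library and were left out. Estimated counts were summed per gene over 35968 genes and rounded. Long non-coding RNAs were not analysed here.

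Genes were kept by the edgeR filter filterByExpr with a minimum count of 10, which left 18944 genes, and libraries were scaled by TMM, with factors from 0.933 to 1.07. Differential expression was tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with 1 mean per group, 4 libraries in each group and 4 in each of the others. The biological coefficient of variation was 0.0852. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 18944 genes of each of 5 contrasts. These were paused against normal culture in wild-type and in KO cells, the difference of these 2 responses (the interaction), and KO against wild type in normal and in paused culture. The threshold was an adjusted p of 0.05, and "rose", "fell" and "changed" refer to it. Log2 fold changes are given with an SE derived as the absolute log2 fold change divided by the square root of the F statistic. CPM are given with the SD over 4 libraries.

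Gene lists were fixed before the data were examined, 39 in all, of which 38 had enough tested members. They cover microRNA machinery and targets, pluripotency and lineage markers, ribosomes, mTOR, metabolism, stress, cell cycle, chromatin and signalling. Lists with fewer members tested than listed were endoderm (12 of 14), mesoderm (11 of 12), neuroectoderm (8 of 10), fibroblast (11 of 16), 2-cell-like (13 of 14), interferon (18 of 22), imprinted (21 of 29), ECM (23 of 25) and sex chromosome genes (4 of 7). Each list was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 38 lists of each contrast, and again with a correlation estimated from the data. Members are counted as higher or lower by the adjustment over all genes, and beside it by an adjustment over the list alone.

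Genes named in the text were chosen by rule. Per contrast these are the 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold with a mean log2 CPM of at least 3, with no overlap between the 4 and 4 libraries (not asked of the interaction), without predicted gene models, Rik names and genes annotated as pseudogenes. Not all of these 20 are described. Added are members of the lists with the largest changes and 24 genes fixed before the data were examined, among them Dgcr8, Drosha, Dicer1, Lats2, Cdkn1a, Myc, Mycn, Klf4, Nanog, Dnmt3b, Fgf5, Ddit4 and Mtor. For genes without counts in a group the ratio is a bound against 3 counts over the group, and for 1 to 3 counts a ratio with a 95% counting interval is given.

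Library measures were compared with exact permutation tests over all divisions of 4 and 4 libraries, two-sided, adjusted over 20 tests. Replicates were compared by the median chi-square per gene for genes with at least 100 counts. Chromosomal position was examined for protein-coding genes with a mean log2 CPM of at least 3, in windows of 10 Mb with at least 10 genes, with a shift of 0.4 in median log2 fold change in both cultures and 100 shuffles of gene order, and segments were runs of genes on a running median of 11 genes. Response sizes were taken by picking genes with 2 replicates per group and measuring them in the 2 others. Sites for microRNAs were counted in the longest 3′ UTR of each gene, and a linear model with the log2 UTR length and the mean expression gave the site effect, adjusted over 80 tests.

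Recovery of known changes was tested on simulated data, drawn with the mean levels, library sizes and dispersion of these libraries, with 50 changed genes per size and sign, all above a mean of 50 counts. Of changes of 1 on the log2 scale, 94% to 96% were recovered for pausing in wild-type cells, 96% to 100% for pausing in KO cells, 84% to 86% for the interaction, 90% to 98% for Dgcr8 loss in normal culture and 94% to 98% in paused cells. Of changes of 0.5, 64% to 68%, 78%, 60%, 72% to 76% and 64% to 76% were recovered. The share of false calls was 1.83%, 6.38%, 4.61%, 5.08% and 6.21% in the same order. Apart from the changed genes, each gene had the same mean in all groups, and libraries were drawn independently. In the real comparisons 41.9% to 68.2% of genes were called, so the simulated shares may not hold for them.

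Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 4 libraries, length-scaled TPM counts, the replicate number as a block, a fit of only the groups compared, a change of at least 1 on the log2 scale and leaving out each library. Medians of called lists in replicates 1 and 2 and in replicates 3 and 4 were compared after the data were seen. Gene lists were also tested with fry, and site effects with the 6-base core, without covariates and with the 3′ UTR of the most abundant transcript.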

Results

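Messenger RNA was measured by sequencing of poly(A)-selected RNA in mouse embryonic stem cells (ESCs), pluripotent cells that derive from the blastocyst. Cells were wild type or lacked Dgcr8, the RNA-binding partner of the nuclease Drosha in the complex that cuts primary microRNA transcripts. Each genotype was grown in normal medium or with an inhibitor of mTOR, the kinase that couples growth to nutrients, for which the labels give day 2. Inhibition of mTOR is used to hold ESCs in a slowed, dormancy-like state, here called paused, that resembles embryonic diapause. This gave 4 groups of 4 libraries, 16 in all, and the design asks how loss of microRNA maturation changes the entry of pluripotent cells into the paused state. The summed estimated counts of the 4 wild-type libraries in normal culture were 99302184, 109775961, 103034445 and 89035518, and those of the 4 paused wild-type libraries were 95953053, 98005665, 98404003 and 91793641. The knockout (KO) libraries held 98047821, 110782018, 104472221 and 98213005 counts in normal culture and 88377380, 116646028, 101849752 and 94240074 when paused. Totals did not differ between groups in any of the 4 pairs compared (exact permutation test, two-sided, smallest p = 0.40).

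The targeted gene was examined first. Dgcr8 (ENSMUSG00000022718.12, chromosome 16, 18253948 to 18289246, GRCm38) was not lower in the KO libraries but higher. Its level was 47.3 ± 1.81 CPM (counts scaled to library size; SD, n = 4) in wild-type normal culture, with 49.24, 48.28, 45.28 and 46.27 CPM in the single libraries, and 53.9 ± 2.43 CPM in paused wild-type cells (50.77, 53.25, 56.22 and 55.36). In KO cells it reached 250 ± 4.14 CPM in normal culture (246.2, 249.5, 256.1 and 249.4) and 181 ± 7.33 CPM when paused (186.9, 175.8, 187.2 and 173.2). The log2 fold change, KO over wild type, was 2.40 ± 0.04 (SE) in normal culture (adjusted p = 5.4e-18) and 1.75 ± 0.04 when paused (adjusted p = 6.8e-16). The more abundant of the 2 protein-coding transcripts had 50.1 to 68.6 TPM in the 8 KO and 11.3 to 17.1 TPM in the 8 wild-type libraries, and the non-coding Dgcr8-206 had 42.9 to 61.7 against 1.40 to 3.28 TPM. The other protein-coding transcript, Dgcr8-209, had 0 TPM in the KO and 0.397 to 0.695 TPM in the wild-type libraries. The labels do not say which part of the gene was deleted, so a level outside the deleted part checks nothing about the genotype. Of 4 genes of the Y chromosome, 3 separated the genotypes across both cultures. Ddx3y had 8326 to 10946 counts in wild-type and 13 to 44 in KO libraries, Eif2s3y 4604 to 7613 against 8 to 40, and Uty 2649 to 4512 against 33 to 69. Kdm5d separated them only within each culture, with 2.31 to 2.51 CPM in KO against 3.03 to 4.53 in wild-type libraries in normal culture and 4.65 to 6.29 against 6.72 to 7.17 when paused.

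Libraries of 1 group lay close together on the first components of a principal component analysis, where the first component (57.7% of the variance) separated the genotypes and the second (22.6%) separated normal from paused culture. The number of genes detected was 23675 ± 188 in wild-type and 22428 ± 54.9 in KO libraries in normal culture. It was 23628 ± 95.2 and 22634 ± 265 when paused (SD, n = 4; exact permutation test, p = 0.0286 for each, the smallest possible, and 0.0952 after Benjamini-Hochberg adjustment over 20 tests). The share of counts in pseudogenes was 7.74% ± 1.64 in normal and 4.51% ± 0.162 in paused wild-type cells (exact p = 0.0286, 0.0952 after adjustment), and 4.64% ± 1.67 and 3.68% ± 0.333 in KO cells (exact p = 0.343). In wild-type normal culture most of that share was a single processed pseudogene, Gm19220, with 53550 ± 20000 CPM against 14860 ± 1430 CPM in paused wild-type cells. Mitochondrially encoded mRNAs took 1.63% to 1.85% of counts in the group means. Wild-type replicates 1 and 2 stood apart from replicates 3 and 4 in normal culture, with a median chi-square per gene of 1.24 to 1.49 within these pairs and 7.65 to 10.7 across them. Paused wild-type libraries split the same way, with 1.21 to 1.88 within and 3.01 to 3.87 across these pairs. So did KO libraries in normal culture, with 1.60 to 2.42 within and 2.84 to 4.04 across. In paused KO cells replicates 1 and 3 stood apart from 2 and 4, with 1.95 to 2.19 within and 2.76 to 4.45 across. Because the labels do not say that replicates were separate cultures, the p-values measure only the spread between these samples, which may be technical.

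**Figure D1:**
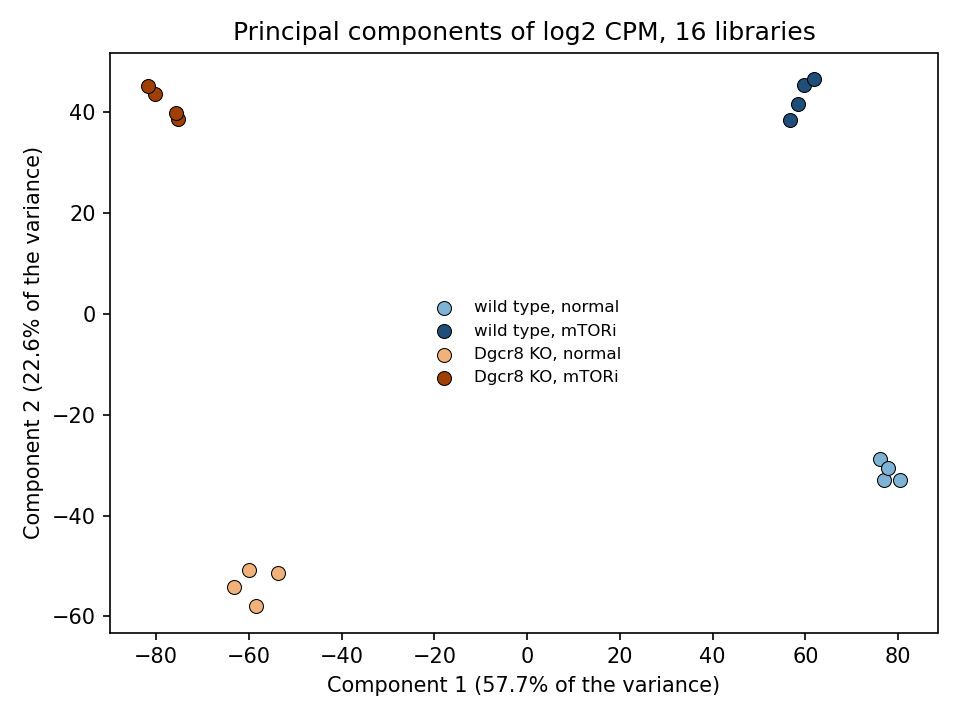
Scores of the 16 libraries on the first and second principal components of log2 CPM, in arbitrary units, coloured by group. The first component (57.7% of the variance) separates KO from wild-type libraries and the second (22.6%) separates paused from normal culture.

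The first comparison asked what mTOR inhibition did in wild-type cells. Among genes with a mean log2 CPM of at least 3 that met the rule for naming, the 10 largest falls were those of Nupr1, Ddit4, Chac1, Mthfd2 and Psat1, and Ubap1l (−3.43), Klhl13 (−2.44), Slc6a9 (−2.39), Fetub (−2.39) and AU015836 (−2.34). Nupr1, a stress-induced chromatin protein (ENSMUSG00000030717.9, chromosome 7, 126623249 to 126630861), went from 11.3 ± 3.80 to 0.469 ± 0.0462 CPM (SD, n = 4). This was a log2 fold change of −4.59 ± 0.28 (SE). Chac1, which degrades glutathione (ENSMUSG00000027313.3, chromosome 2, 119351229 to 119354381), fell by 2.79 ± 0.12 on the log2 scale, Mthfd2, an enzyme of mitochondrial folate metabolism, by 2.72 ± 0.08, and Ddit4, an inhibitor of mTOR signalling, by 2.83 ± 0.25. Psat1, an enzyme of serine synthesis, fell by 2.35 ± 0.15. Among the genes that rose, the guanine nucleotide exchange factor Arhgef28 gained 2.90 ± 0.15 and the pro-apoptotic BH3-only gene Bmf 2.24 ± 0.07. The translation initiation scaffold Eif4g3 (ENSMUSG00000028760.16, chromosome 4, 137993022 to 138208508) rose by 2.32 ± 0.07, from 25 ± 2.09 to 125 ± 10.8 CPM. The naive pluripotency factor Klf4 rose from 153 ± 3.71 to 336 ± 3.71 CPM, and Myc by 0.68 ± 0.15 while Mycn fell by 0.56 ± 0.11. All of these had an adjusted p of 0.00086 or less, and edgeR's quasi-likelihood test called 11507 of 18944 genes at an adjusted p under 0.05, 6303 higher and 5204 lower. The excess of higher genes depends on the fit. A fit of only these groups gave 5391 higher and 5394 lower. A change of at least 1 on the log2 scale was met by 1163 of the higher and 790 of the lower genes.

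Of the gene lists, 10 shifted in paused wild-type cells. The number of members adjusted over the list alone is given in brackets where it differs. ATF4 and amino acid response genes were lower in 17 of 20 members and higher in 0, with a median log2 fold change of −0.98 (adjusted p = 6.7e-12, adjusted p = 0.31 with an estimated correlation). The largest changes were those of Chac1, Mthfd2, Psat1 and the pseudokinase Trib3 (−2.20). Oxidative phosphorylation subunits were lower in 41 of 48 members (42 adjusted over the list alone) and higher in 2, led by cytochrome c (Cycs, −1.01) and Ndufb10 (−0.94), with adjusted p = 2.4e-12 and adjusted p = 0.31 with an estimated correlation. Ribosome biogenesis factors were lower in 27 of 31 members and higher in 1, among them Nop16 (−1.06) and Ddx21 (−0.85; adjusted p = 7.8e-12, adjusted p = 0.31 with an estimated correlation). G1/S and DNA replication genes were lower in 16 of 24 (17 adjusted over the list alone) and higher in 3, with cyclin E1 (Ccne1) at −1.14 and the ribonucleotide reductase subunit Rrm2 at −0.99 (adjusted p = 1.1e-05, adjusted p = 0.31 with an estimated correlation). Heat shock and unfolded protein response genes were lower in 15 of 20 and higher in 2 , with the chaperones Hspa1b at −1.22 and Hspd1 at −1.03 (adjusted p = 9e-05, adjusted p = 0.31 with an estimated correlation). NRF2-type oxidative stress genes were lower in 9 of 15 and higher in 2, with haem oxygenase (Hmox1) at −1.82 (adjusted p = 0.011, adjusted p = 0.31 with an estimated correlation).

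In the same comparison, sterol and fatty acid synthesis genes were lower in 18 of 26 and higher in 1, with the desaturase Scd1 at −1.69 (adjusted p = 2e-05, adjusted p = 0.56 with an estimated correlation). Of the p53 targets 15 of 21 were lower (16 adjusted over the list alone) and 3 higher, led by the kinase Plk2 (−1.89) and the desmosome protein Perp (−1.88; adjusted p = 0.001, adjusted p = 0.56 with an estimated correlation). Glycolysis genes were lower in 12 of 20 (13 adjusted over the list alone) and higher in 4 (5 over the list alone), with lactate dehydrogenase (Ldha) at −2.28 ± 0.14 and triose phosphate isomerase (Tpi1) at −1.92 ± 0.15 (adjusted p = 0.0051, adjusted p = 0.56 with an estimated correlation). Ldha, Tpi1 and Pgk1 have processed pseudogenes that can share reads with them, so the size of their change is uncertain. Lysosome and autophagy genes of the TFE3/TFEB type were higher in 18 of 35 and lower in 6, with the autophagy protein Wipi1 at 1.77 and the protease Ctsa at 0.95 (adjusted p = 0.011, adjusted p = 0.46 with an estimated correlation). Targets of ESC cell-cycle microRNAs, chosen as known targets of the miR-290 family, were higher in 7 of 11 members, lower in 1 (2 adjusted over the list alone), with the Hippo kinase Lats2 at 1.54 ± 0.13, but the list did not pass (adjusted p = 0.057). Replicates 1 and 2 alone gave 11180 called genes and replicates 3 and 4 alone 10996. Of the 10 lists with a call, 5 had medians that differed by over 1.5 times between the former and the latter. They were NRF2-type (−0.10 and −0.27), glycolysis (−0.72 and −0.28), p53 targets (−1.11 and −0.50), lysosome and autophagy (0.13 and 0.24) and sterol and fatty acid synthesis (−0.21 and −0.34). Medians had opposite signs for mesoderm (0.33 and −0.27), neuroectoderm (0.19 and −0.33) and 2-cell-like markers (0.04 and −0.75), lists without a call here.

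The second comparison made the same contrast in Dgcr8 KO cells. By the same rule the 10 largest falls were those of Pcdhgc4, 4 genes of the Zscan4 family, Lefty2, Lefty1, Ldha, Scd2 and Tpi1. The Zscan4 genes, of which 1 is named a pseudogene but annotated as protein-coding, share reads, had few counts in KO cells and are not read further here. Lefty2, a secreted Nodal inhibitor (ENSMUSG00000066652.5, chromosome 1, 180893108 to 180899103), went from 68.2 ± 14.1 to 3.90 ± 1.10 CPM (SD, n = 4; log2 fold change −4.14 ± 0.29, SE), and the neighbouring Lefty1 fell by 2.79 ± 0.31. The fatty acid desaturase Scd2 (ENSMUSG00000025203.6, chromosome 19, 44293674 to 44306864) fell by 3.17 ± 0.06, from 676 ± 54.3 to 75.1 ± 4.91 CPM. Ldha (ENSMUSG00000063229.15, chromosome 7, 46841475 to 46855627) fell by 3.24 ± 0.15 and Tpi1 by 2.99 ± 0.16, both with pseudogenes that can share reads. Eif4g3 rose by 3.25 ± 0.07, the neural transcription factor Sox21 by 3.21 ± 0.22, and Irs2, an adaptor of the insulin receptor, by 2.42 ± 0.06. Pcdhgc4, a protocadherin, fell by 5.17 ± 0.23, a value that is uncertain because the transcripts of its cluster share their last exons. Klf4 rose by 0.72 ± 0.04 and Nanog by 0.36 ± 0.05, whereas Chac1 (91.7 ± 6.52 and 96.7 ± 11.6 CPM) did not pass the test. In all, edgeR called 12727 genes, 6521 higher and 6206 lower, of which 1749 and 1152 changed by at least 1 on the log2 scale.

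Of the lists, 10 shifted in paused KO cells. All 26 sterol and fatty acid synthesis genes were lower, with a median log2 fold change of −1.15 and with Scd2 at −3.17 and the isoprenoid enzyme Idi1 at −1.88 (adjusted p = 4.6e-30, adjusted p = 0.14 with an estimated correlation). G1/S and DNA replication genes were lower in 21 of 24 and higher in 0, led by Ccne1 (−2.69) and cyclin D2 (Ccnd2, −1.71; adjusted p = 9.4e-14, adjusted p = 0.14 with an estimated correlation). Ribosome biogenesis factors were lower in 29 of 31 and higher in 0, with Nop16 at −1.33 (adjusted p = 2.3e-11, adjusted p = 0.31 with an estimated correlation). Oxidative phosphorylation subunits were lower in 40 of 48 and higher in 2, with Cycs at −1.47 (adjusted p = 1e-08, adjusted p = 0.39 with an estimated correlation). Glycolysis genes were lower in 16 of 20 and higher in 3, with the lactate exporter Slc16a3 at −2.64 (adjusted p = 5.3e-08, adjusted p = 0.31 with an estimated correlation). Heat shock and unfolded protein response genes were lower in 15 of 20 and higher in 3, with Hspa1b at −1.88 (adjusted p = 9.7e-06, adjusted p = 0.19 with an estimated correlation). Lysosome and autophagy genes were higher in 23 of 35 and lower in 3, with the calcium channel Mcoln1 at 1.27 and Ctsa at 1.21 (adjusted p = 2.6e-06, adjusted p = 0.19 with an estimated correlation). Germline genes kept off by DNA methylation were higher in 9 of 15 and lower in 3, with the synaptonemal complex gene Sycp2 at 2.57 and the RNA-binding protein Dazl at 1.81 (adjusted p = 0.011, adjusted p = 0.34 with an estimated correlation). G2/M genes (15 of 22 lower, 4 higher; adjusted p = 0.04, adjusted p = 0.67 with an estimated correlation) and p53 targets (11 of 21 lower, 0 higher; adjusted p = 0.046, adjusted p = 0.85 with an estimated correlation) were near the threshold, and both calls were lost when a term for replicates 1 and 2 against 3 and 4 was added. ATF4 and amino acid response genes were lower in 9 of 20 members and higher in 2, and the list did not pass (median −0.14, adjusted p = 0.43). Of the 10 lists with a call, none had medians that differed by over 1.5 times between replicates 1 and 2 and replicates 3 and 4.

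Whether the response differed between the genotypes was tested as an interaction, the log2 fold change of pausing in KO cells minus that in wild-type cells. Nupr1 differed by 4.13 ± 0.34 (SE), Chac1 by 2.87 ± 0.16, the glycine transporter Slc6a9 by 2.72 ± 0.23 and the mitochondrial folate enzyme Aldh1l2 by 2.50 ± 0.36. The trophoblast and germ cell factor Tfap2c, which fell by 1.27 ± 0.08 in wild-type cells and rose by 1.19 ± 0.08 in KO cells, differed by 2.46 ± 0.11. In the other direction Lefty2 differed by −4.45 ± 0.38, Lefty1 by −2.94 ± 0.41, the Wnt effector Lef1 by −2.19 ± 0.35 and the cytoskeletal gene Sptb by −2.07 ± 0.13. Myc rose in wild-type cells and fell in KO cells (interaction −1.13 ± 0.21), and the reverse held for Mycn (1.07 ± 0.15). The plot of single libraries shows 6 genes, among them Nupr1, Chac1 and Lefty2. In all, edgeR called 7936 genes with an interaction, 3293 positive and 4643 negative, of which 867 and 792 differed by at least 1.

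**Figure D2:**
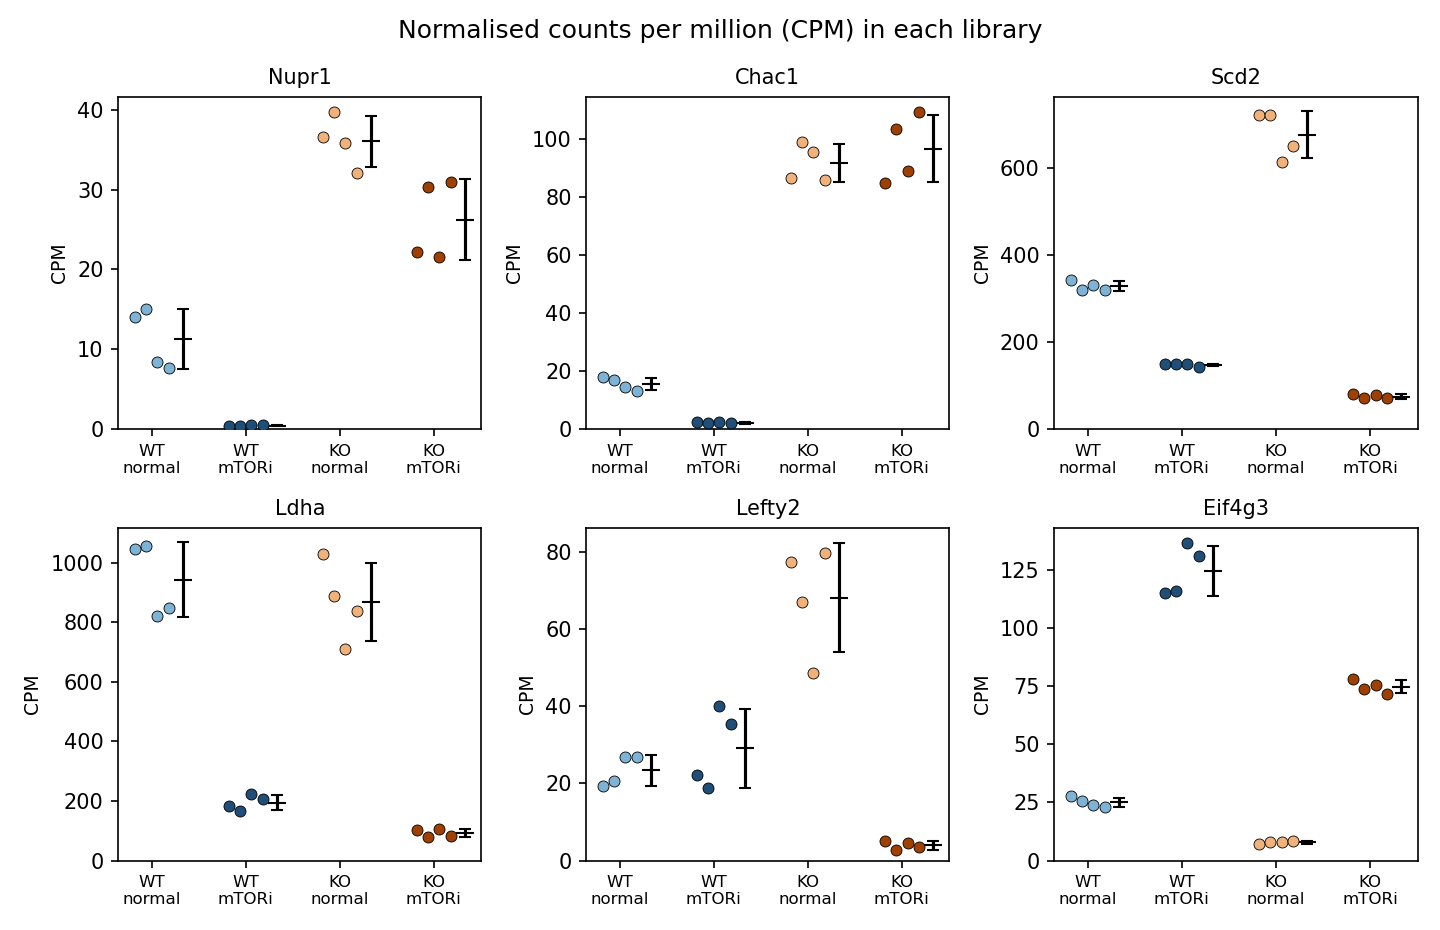
CPM of 6 named genes in each of the 16 libraries (points, linear axis from 0) with the mean and SD of each group of 4 libraries (lines). When paused, Nupr1 and Chac1 lie at 0.469 and 2.26 CPM in wild-type and at 26.3 and 96.7 CPM in KO libraries, and Lefty2 lies at 3.90 CPM in KO libraries.

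Interactions of 10 lists passed the test, and for 3 of them the call held with an estimated correlation. Wnt, LIF/STAT3 and TGF-beta signalling genes had a negative interaction in 15 of 23 members (17 adjusted over the list alone) and a positive one in 5 (adjusted p = 8.3e-06, adjusted p = 0.028 with an estimated correlation). Apoptosis regulators were negative in 12 of 20 and positive in 0 (1 adjusted over the list alone), with the BH3-only gene Bmf at −1.11 and the initiator caspase Casp8 at −1.17 (adjusted p = 0.00011, adjusted p = 0.028 with an estimated correlation). Targets of ESC cell-cycle microRNAs were negative in 5 of 11 (6 adjusted over the list alone) and positive in 0 (1 adjusted over the list alone), among them the GTPase Rhoc (−1.46) and the TGF-beta receptor Tgfbr2 (−1.03), with adjusted p = 0.00049 and adjusted p = 0.028 with an estimated correlation. A negative value means that a gene rose by more, or fell by less, in wild-type than in KO cells.

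The other 7 calls did not hold with an estimated correlation. Sterol and fatty acid synthesis genes were negative in 25 of 26, with Scd2 at −2.02 (adjusted p = 3.3e-26, adjusted p = 0.071 with an estimated correlation). ATF4 and amino acid response genes were positive in 17 of 20 and negative in 0, with Trib3 at 1.89 and Mthfd2 at 1.87 (median 0.81; adjusted p = 4.1e-14, adjusted p = 0.30 with an estimated correlation). G1/S genes were negative in 15 of 24 (16 adjusted over the list alone) and positive in 0 (1 adjusted over the list alone), with Ccne1 at −1.55 (adjusted p = 7.3e-06, adjusted p = 0.34 with an estimated correlation). Glycolysis genes were negative in 14 of 20 (15 adjusted over the list alone) and positive in 1, with Slc16a3 at −1.93 (adjusted p = 0.00014, adjusted p = 0.57 with an estimated correlation). Lysosome and autophagy genes were positive in 16 of 35 and negative in 4 (6 adjusted over the list alone), with the Rag GTPase Rragd at 1.22 (adjusted p = 0.0035, adjusted p = 0.44 with an estimated correlation). G2/M genes were negative in 12 of 22 (14 adjusted over the list alone) and positive in 1 (adjusted p = 0.0073, adjusted p = 0.57 with an estimated correlation). Trophoblast markers were positive in 5 of 11 (7 adjusted over the list alone) and negative in 1 (2 adjusted over the list alone), with Tfap2c at 2.46 and the imprinted factor Ascl2 at 1.11 (adjusted p = 0.0073, adjusted p = 0.33 with an estimated correlation). Between replicates 1 and 2 and replicates 3 and 4, 6 of the 10 medians differed by over 1.5 times. They were those of lysosome and autophagy (0.08 and 0.21), microRNA targets (−0.32 and −0.15), Wnt, LIF/STAT3 and TGF-beta signalling (−0.28 and −0.53), G1/S (−0.44 and −0.28), sterol and fatty acid synthesis (−0.91 and −0.59) and apoptosis regulators (−0.56 and −0.36).

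**Figure D3:**
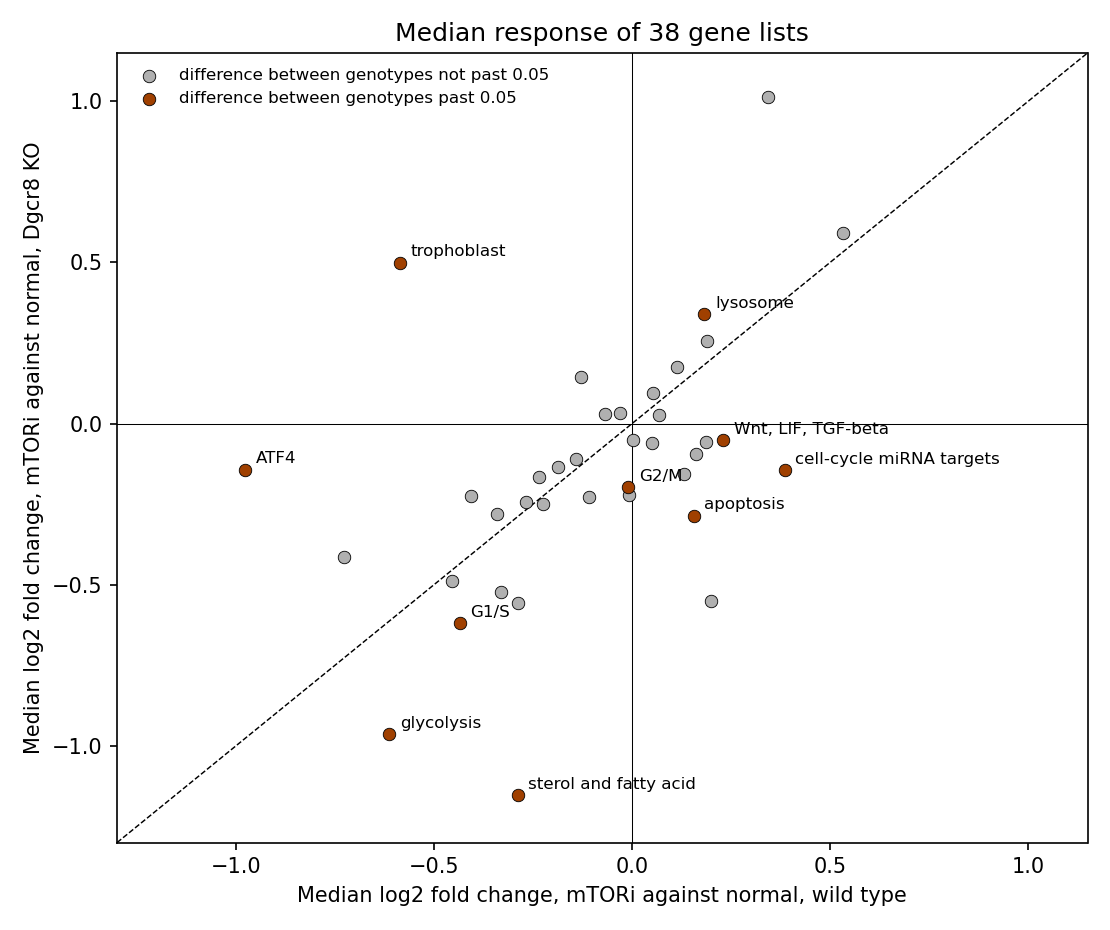
Median log2 fold change on pausing in wild-type cells (horizontal axis) against that in KO cells (vertical axis) for the 38 tested gene lists, 1 point each, with the line of equal change. The 10 lists named have an interaction past adjusted p 0.05; the ATF4 list lies at −0.98 and −0.14 and the sterol list at −0.29 and −1.15.

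Across genes, which are not independent replicates, the fold changes of pausing in the 2 genotypes correlated with Pearson's r = 0.579 and Spearman's rho = 0.594, with no library shared between the contrasts. Higher calls were shared for 4141 genes, where independent lists would share 2170, and lower calls for 3836, where they would share 1705. Of the 8963 genes called in both genotypes, 986 (11%) went in opposite directions. Genes picked in wild-type cells with 2 replicates per group had a mean signed change of 0.73 in the held-out wild-type replicates and 0.59 in KO cells, a median ratio of 0.813 over 6 choices of replicates (range 0.761 to 0.863). Genes picked in KO cells changed by 0.69 in held-out KO replicates and 0.42 in wild-type cells, a ratio of 0.597 (0.580 to 0.603). No test was made of these ratios.

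Loss of Dgcr8 in normal culture was compared next. Moxd1, a monooxygenase-like protein, rose by 4.61 ± 0.19 (SE), the AP-1 family repressor Jdp2 by 4.02 ± 0.14, mitochondrial PEP carboxykinase (Pck2) by 3.37 ± 0.11, the lipoprotein receptor Vldlr by 3.33 ± 0.20 and Aldh1l2 by 3.30 ± 0.24. Klf4 rose from 153 ± 3.71 to 407 ± 19.3 CPM (SD, n = 4), and the cell cycle inhibitor Cdkn1a by 0.54 ± 0.14. Dnmt3b, a de novo DNA methyltransferase, fell from 477 ± 46.4 to 89.5 ± 10.6 CPM, Mycn by 1.01 ± 0.11, and the ubiquitin ligase adaptor Klhl13 by 5.25 ± 0.22. Among the genes with the largest falls were Ddx3y and Eif2s3y on the Y chromosome and members of the Zscan4 family, markers of rare cells that resemble the 2-cell embryo. In all, edgeR called 12923 genes, 6463 higher and 6460 lower, of which 1512 and 2526 changed by at least 1 on the log2 scale.

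Whole chromosomal regions shifted together in KO cells. On chromosome 1 the median log2 fold change of 536 protein-coding genes with sufficient expression was 0.67 in normal culture and 0.61 when paused. It was 0.07 and 0.00060 for 8398 genes of the other autosomes outside the segments named next. Of the 536 genes, 501 (93.5%) were above 0 in normal culture. A segment of chromosome 14 (43.9 to 63.2 Mb) had a median of 0.93 in normal and 0.88 in paused culture over 122 genes. Segments of chromosome 6 (79.8 to 99.5 Mb, 88 genes) and chromosome 10 (45.6 to 71.2 Mb, 64 genes) had medians of −0.83 and −0.78 in normal culture and of −0.99 and −0.88 when paused. Of 236 windows of 10 Mb, 23 were shifted in both cultures. Of these, 1 on chromosome 10 lies outside these regions (14 genes, medians −0.55 and −0.45). Examples among the genes named here are Lefty1, Lefty2, Casp8 and Atf3 on chromosome 1 and Pck2 and Lats2 in the segment of chromosome 14. Ddit4 lies in that of chromosome 10 and Mthfd2 in that of chromosome 6. Other named genes may also lie in these regions. Without these regions and the Y chromosome, 11637 genes were called in normal culture and 11128 when paused.

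**Figure D4:**
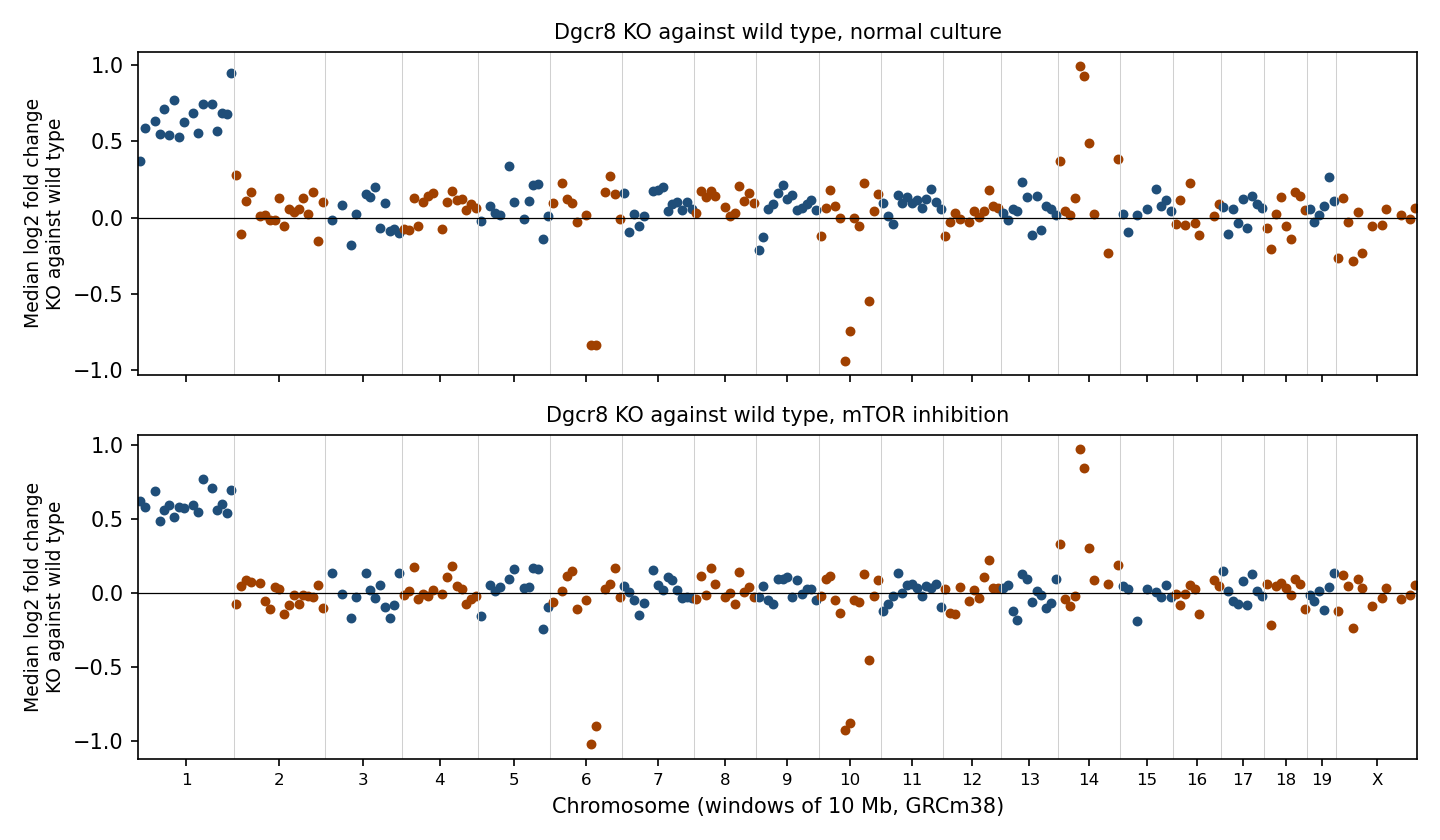
Median log2 fold change, KO over wild type, of genes in windows of 10 Mb along the chromosomes (horizontal axis, in genome order), in normal culture and when paused. Windows of chromosome 1 and of a segment of chromosome 14 lie above 0 and those of segments of chromosomes 6 and 10 below it in both cultures.

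Of the lists, 14 shifted with Dgcr8 loss in normal culture, and only the call of the sex chromosome list held with an estimated correlation. That list, nuclear RNA and sex chromosome genes, was lower in 4 of 4 tested members (adjusted p = 1.7e-31, adjusted p = 3.3e-06 with an estimated correlation). Its tested members include Ddx3y, Eif2s3y and Uty, the Y chromosome genes that were nearly absent from all KO libraries. Whether this is an effect of Dgcr8 loss or a difference between the lines cannot be told apart. Targets of ESC cell-cycle microRNAs were higher in 8 of 11 members and lower in 1, with Tgfbr2 at 2.41, Rhoc at 0.99 and Lats2 at 0.93 (adjusted p = 0.015, adjusted p = 0.087 with an estimated correlation). Lats2 lies in the shifted segment of chromosome 14, whose median was also 0.93. The microRNA biogenesis and effector machinery was higher in 11 of 18 members and lower in 4 (5 adjusted over the list alone), with Dgcr8 itself, Argonaute 2 (Ago2, 0.70) and the GW182 protein Tnrc6a (0.68), and the call was lost with length-scaled counts (adjusted p = 0.014, adjusted p = 0.32 with an estimated correlation). ATF4 and amino acid response genes were higher in 16 of 20 and lower in 0, with Atf3 at 3.21 and Chac1 at 2.55 (adjusted p = 2e-08, adjusted p = 0.32 with an estimated correlation). Sterol and fatty acid synthesis genes were higher in 24 of 26 (25 adjusted over the list alone) and lower in 0, with Scd1 at 1.91 and Dhcr7, an enzyme of cholesterol synthesis, at 1.20 (adjusted p = 4e-10, adjusted p = 0.30 with an estimated correlation). Glycolysis genes were higher in 12 of 20 and lower in 2 (adjusted p = 0.039, adjusted p = 0.74 with an estimated correlation).

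All 13 tested 2-cell-like markers were lower in KO cells (adjusted p = 1.7e-12, adjusted p = 0.087 with an estimated correlation). Their median log2 fold change was −6.10 with the 7 members at 3 counts or fewer in the KO group set to a floor of 3 counts over the group. Tcstv3 had no counts in KO normal culture and was at least 116.9-fold lower, and Tcstv1 at least 27.9-fold lower. Zfp352, with 3 counts in the group, was lower by a ratio of 203 (95% counting interval 69.5 to 984; intervals and floors cover counting error only). The 9 genes of the Zscan4 family, which share reads and are uncertain one by one, together held 294 ± 15.6 CPM in wild-type and 1.43 ± 0.340 CPM in KO cells (SD, n = 4). Germline genes were lower in 10 of 15 and higher in 0, with the meiotic gene Hormad1 at −3.19 and Dazl at −2.23 (adjusted p = 2.7e-05, adjusted p = 0.087 with an estimated correlation). Imprinted genes were lower in 14 of 21 and higher in 5, with the zinc finger gene Plagl1 at −5.08 and the growth factor Igf2 at −3.32 (adjusted p = 0.0046, adjusted p = 0.087 with an estimated correlation). Endoderm markers were lower in 11 of 12 and higher in 1, among them Cubn (−3.03) and Foxa2 (−2.87; adjusted p = 0.0086, adjusted p = 0.53 with an estimated correlation). Formative and primed pluripotency genes were lower in 8 of 12 and higher in 2, with Dnmt3b at −2.42 and Fgf5 at −2.36 (adjusted p = 0.014, adjusted p = 0.53 with an estimated correlation). Trophoblast markers were lower in 7 of 11 and higher in 1, with Gata3 at −3.44 (adjusted p = 0.014, adjusted p = 0.30 with an estimated correlation). DNA methylation regulators were lower in 5 of 11 and higher in 2, with a median of −0.05 and a mean of −0.58, and the call was lost without the shifted regions (adjusted p = 0.038, adjusted p = 0.30 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 48 of 76 and higher in 5, with a median of −0.14 (adjusted p = 0.039, adjusted p = 0.91 with an estimated correlation). The call was lost with length-scaled counts. Reads shared with processed pseudogenes may affect this median, which was not tested. Of the 14 medians 5 differed by over 1.5 times between replicates 1 and 2 and replicates 3 and 4. They were those of DNA methylation regulators (−0.27 and −0.02), trophoblast markers (−0.43 and −0.94), germline genes (−0.50 and −0.85), glycolysis (0.55 and 0.33) and sterol and fatty acid synthesis (0.99 and 0.63).

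The last comparison was that of Dgcr8 loss in paused cells. Nupr1 rose by 5.80 ± 0.27 (SE), from 0.469 ± 0.0462 to 26.3 ± 5.08 CPM (SD, n = 4), Aldh1l2 by 5.80 ± 0.28, Vldlr by 5.46 ± 0.23, Chac1 by 5.42 ± 0.13 and the secreted glycoprotein Stc2 by 4.57 ± 0.20. Nanog rose from 407 ± 32.3 to 689 ± 17.7 CPM and Klf4 from 336 ± 3.71 to 669 ± 23.7 CPM, whereas Myc fell from 166 ± 5.44 to 57.6 ± 10 CPM and the cell cycle inhibitor Cdkn1c by 3.97 ± 0.20. Lats2 rose by 1.32 ± 0.12 and Cdkn1a by 0.72 ± 0.14. In all, edgeR called 12385 genes, 5844 higher and 6541 lower, of which 1224 and 2238 changed by at least 1 on the log2 scale. Across genes, which are not independent replicates, the effects of Dgcr8 loss in the 2 cultures correlated with r = 0.830 (rho = 0.682), with no library in common. Genes higher in both numbered 4288 where independent lists would share 1994, genes lower in both 4363 where they would share 2231, and 1005 of 9656 genes called in both (10.4%) went in opposite directions.

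Lists shifted in 12 cases in paused cells, and again only the call of the sex chromosome list (4 of 4 lower) held with an estimated correlation (adjusted p = 5.8e-35, adjusted p = 8.6e-07 with an estimated correlation). The limit given for this list in normal culture holds here too. ATF4 and amino acid response genes were higher in 19 of 20 and lower in 0, with a median of 1.74 and Trib3 at 4.00 (adjusted p = 7.9e-28, adjusted p = 0.12 with an estimated correlation). All 13 of the 2-cell-like markers were lower, with a median of −6.49 at the floor and Zfp352 at least 174.7-fold lower (adjusted p = 4.1e-14, adjusted p = 0.12 with an estimated correlation). Formative and primed pluripotency genes were lower in 10 of 12 and higher in 1, with Lef1 at −3.91 and Pou3f1 at −2.56 (adjusted p = 4.9e-05, adjusted p = 0.22 with an estimated correlation). Lysosome and autophagy genes were higher in 23 of 35 and lower in 5, with the lysosomal enzyme Naglu at 1.51 (adjusted p = 0.00063, adjusted p = 0.20 with an estimated correlation). DNA methylation regulators were lower in 9 of 11 and higher in 2, with Dnmt3b at −2.53 and its cofactor Dnmt3l at −1.35 (adjusted p = 0.0023, adjusted p = 0.13 with an estimated correlation). Germline genes were lower in 8 of 15 and higher in 2 (adjusted p = 0.0036, adjusted p = 0.18 with an estimated correlation), and imprinted genes lower in 13 of 21 and higher in 6 (adjusted p = 0.013, adjusted p = 0.18 with an estimated correlation). Endoderm markers were lower in 12 of 12 (adjusted p = 0.007, adjusted p = 0.61 with an estimated correlation). FGF/ERK and feedback genes were lower in 10 of 16 and higher in 2, with the phosphatase Dusp4 at −1.53 (adjusted p = 0.017, adjusted p = 0.18 with an estimated correlation). G2/M genes (14 of 22 lower, 2 higher; adjusted p = 0.017, adjusted p = 0.66 with an estimated correlation) and Wnt, LIF/STAT3 and TGF-beta genes (14 of 23 lower, 5 higher; adjusted p = 0.021, adjusted p = 0.18 with an estimated correlation) also shifted, and both calls were lost without the shifted regions. Between replicates 1 and 2 and replicates 3 and 4, 2 of the 12 medians differed by over 1.5 times. They were those of FGF/ERK and feedback genes (−0.37 and −0.21) and endoderm markers (−1.44 and −0.86). Sterol and fatty acid synthesis genes, which were higher in KO cells in normal culture, were higher in 8, lower in 7 and not past the threshold in 11 of 26 members when paused (median −0.02, adjusted p = 0.72). The targets of ESC cell-cycle microRNAs were higher in 5 and lower in 3 of 11 (adjusted p = 0.83).

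Other lists had no call in any of the 5 comparisons. Naive and core pluripotency genes were higher in 12 and lower in 3 of 20 on pausing of wild-type cells (adjusted p = 0.072) and higher in 11 and lower in 5 in KO cells (adjusted p = 0.075), with the maternal factor Dppa3 at −1.84 in wild-type cells. Genes associated with embryonic diapause and dormancy were higher in 13 and lower in 6 of 23 on pausing in each genotype (7 lower in KO cells adjusted over the list alone; adjusted p = 0.085 in wild-type and 0.27 in KO cells). The fatty acid oxidation enzyme Cpt1a, a member of that list, rose by 1.42 in wild-type cells. In the list of the mTOR pathway and translational control, 12 of 26 were higher and 9 lower (10 adjusted over the list alone) on pausing of wild-type cells (adjusted p = 0.43), with the insulin receptor substrate Irs1 at 2.28 and Ddit4 at −2.83. Cell cycle inhibitors and Rb family genes were higher in 5 and lower in 3 of 13 (4 adjusted over the list alone; adjusted p = 0.52), and let-7 targets higher in 2 and lower in 6 of 13 (adjusted p = 0.28). Splicing factors and nuclear speckle proteins were higher in 9 and lower in 15 of 33 (adjusted p = 0.12), and mitochondrially encoded mRNAs higher in 0 and lower in 5 of 13 (adjusted p = 0.21) in the same comparison. Polycomb and chromatin repressors were higher in 7 and lower in 9 of 21 (adjusted p = 0.93), and interferon response genes higher in 5 and lower in 3 of 18 (adjusted p = 0.93). ECM, adhesion and EMT genes were higher in 7 and lower in 5 of 23 (adjusted p = 0.93, with a positive median of 0.05 and a negative mean of −0.12). As markers of other cell types, mesoderm and primitive streak genes were higher in 2 and lower in 3 of 11 (adjusted p = 0.87). Neuroectoderm genes were higher in 3 and lower in 4 of 8 (adjusted p = 0.93), and fibroblast and feeder cell genes higher in 4 and lower in 4 of 11 (5 adjusted over the list alone; adjusted p = 0.93). None of the 17 primary microRNA host transcripts was analysed here.

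A last question was whether genes with sites for ESC microRNAs rose when Dgcr8 was lost. Over 16661 genes with a 3′ UTR, 2915 carried a site AGCACTT for the miR-290 and miR-302 family. After 3′ UTR length and expression were taken into account, their log2 fold change was higher by 0.020 (SE 0.023) in normal culture (adjusted p = 0.63 over 80 tests) and by 0.038 (SE 0.024) in paused cells (adjusted p = 0.35), which did not pass, though both passed with the 6-base core and without covariates. The 6-base core GCACTT ranked 8 of 180 words of the same base composition in normal culture and 6 of 180 when paused. In normal culture, site effects passed the test for TACTTGA (miR-26, −0.108, adjusted p = 0.0035), TGTTTAC (miR-30, −0.0725, adjusted p = 0.027) and ATAAGCT (miR-21, −0.0901, adjusted p = 0.039), and so did the control site ACACTCC of miR-122 in normal (0.0933, adjusted p = 0.019) and in paused culture (0.0956, adjusted p = 0.019). Sites CAGTATT of miR-200b had a positive interaction of 0.0503 (adjusted p = 0.019) and an effect of 0.0501 on pausing of KO cells (adjusted p = 0.049). With camera no site passed in any comparison (smallest adjusted p = 0.698). In genes with a mean log2 CPM of at least 3 these calls were lost, with −0.0367 for TACTTGA, −0.0195 for TGTTTAC, −0.0426 for ATAAGCT, 0.0328 and 0.0224 for ACACTCC and 0.0344 and 0.0014 for CAGTATT, in the order above (adjusted p from 0.077 to 0.996). The model takes genes as independent, which they are not, so a control site past the threshold shows how far its p-values can be trusted.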

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

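Of the tests reported here, those of scaling and of position for the patterns below, and all tests on the 2-cell-like genes, were chosen only after the result was seen, as was the use of replicate pairs and of the shifted regions. The bounds for the ATF4 list in these, and the test on other splits of the samples, were set before their values were seen.

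The response to pausing differed between the genotypes for 7936 genes by the interaction test. Of 100 splits of the libraries, 3 gave as many genes, the real one included, but these splits do not decide on chance. The 96 that mixed the genotypes in both cultures put the genotype effect into the spread and gave 0 genes by edgeR (at most 3500 at an unadjusted p under 0.05). The 4 others, too few for a share under 0.05, were the real one and splits with 5616, 10608 and 13913 genes. The highest exchanged the genotypes within the paused libraries, which points to a structure of the samples, the genotype effect itself. For pausing in wild-type cells 1 of 35 splits gave as many genes, the real one, with 10785 genes by edgeR in a fit of only these groups, against at most 0 in the others (at most 1182 at an unadjusted p under 0.05). The same held for pausing in KO cells (1 of 35 splits, 12832 genes, at most 0 in the other splits and 949 unadjusted). It held for Dgcr8 loss in normal culture (1 of 35 splits, 11993, 0 and 978). It also held for Dgcr8 loss in paused cells (1 of 35 splits, 12649, 0 and 1398). For each of these 4 comparisons the other splits mixed the groups compared, which put the real difference into the spread. These splits therefore do not decide on chance either.

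Genes of the ATF4 and amino acid response list, which a translation-dependent transcription factor induces when amino acids are short, fell on pausing in wild-type cells and did not pass in KO cells, with a median interaction of 0.81. Scaling moves all genes alike, but the median of the list lay 0.84 above that of the 18924 other tested genes (lower quartile of its members 0.44 above it), which argues against scaling between libraries. Replicates 1 and 2 gave 0.93 and replicates 3 and 4 gave 0.73, which argues against the difference between these pairs. The split of paused KO replicates 1 and 3 against 2 and 4 was not tested. Members outside the shifted chromosomal regions had a median of 0.60. This does not decide on the dosage of the members themselves, since a fixed dosage would move both KO cultures alike and cancel in the interaction. Effects of these regions on genes elsewhere were not tested. Whether loss of Dgcr8 itself or another difference between the lines underlies the pattern was not tested, and the list's call was lost with an estimated correlation (adjusted p = 0.30).

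Genes of chromosome 1 and of segments of chromosomes 6, 10 and 14 shifted as blocks in KO cells. Scaling or depth moves all chromosomes alike, but chromosome 1 lay 0.60 above the other autosomes outside these segments in the culture with the smaller difference. Chance order of genes gave at most 2 shifted windows in 100 shuffles, against 23. An additional copy of chromosome 1 in part or all of the KO cells may be the source, since 93.5% of its genes were higher and the median fold was 1.59 in normal culture, but this was tested on the data in which it was seen. DNA was not analysed here, and effects of Dgcr8 loss cannot be separated from such differences between the lines. The same limit holds for the near absence of Ddx3y, Eif2s3y and Uty of the Y chromosome in KO cells.

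The 2-cell-like genes were nearly absent in KO cells. Reads shared between paralogs would keep the sum of the Zscan4 family, which was lower by a log2 ratio of −7.69 in the culture with the smaller fall. A deletion at a single locus would not itself remove members on 6 chromosomes, but this says nothing about the loss of a factor that acts on them. Loss of the Dux cluster, whose factor activates these genes, cannot be told apart from other causes, since genes within 1 Mb of Duxf3 had a median log2 fold change of −1.20 in normal culture and lie in the shifted segment of chromosome 10. Of these, picked after their values were seen, AW822073 (−7.42), Gm10807 (−6.84) and Gm6494 (−6.11) were nearly absent, while Hsf2 (−1.05), Lims1 (−1.27) and Ranbp2 (−0.85) were not. No biological explanation was tested.

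A difference between the genotypes was also found for these list medians: targets of ESC cell-cycle microRNAs −0.22, trophoblast markers 0.65, glycolysis −0.43, sterol and fatty acid synthesis −0.80, lysosome and autophagy 0.20, G1/S −0.32, G2/M −0.14, apoptosis regulators −0.53 and Wnt, LIF/STAT3 and TGF-beta signalling −0.50. With an estimated correlation only the calls of the microRNA targets, the apoptosis regulators and the signalling list held. Of the named genes it was found for Nupr1 (4.13), Chac1 (2.87), Pcdhga8 (2.81), Slc6a9 (2.72), Klhl13 (2.70), Hhip (2.53), Aldh1l2 (2.50), Sox21 (2.46), Tfap2c (2.46) and Fetub (2.37), and with a negative sign for Lefty2 (−4.45), Pcdhgc4 (−4.19), Lefty1 (−2.94), Khdc3 (−2.43), Ccdc3 (−2.26), Robo4 (−2.24), Lef1 (−2.19) and Sptb (−2.07). The Zscan4 genes Zscan4d (−3.58) and Zscan4c (−2.59) share reads and lie near 0 in KO cells, and the call of Zscan4d is lost on leaving out 1 library, with an adjusted p of up to 0.0856. Of the 24 genes fixed beforehand 15 differed: Dgcr8 (−0.66), Drosha (−0.35), Myc (−1.13), Mycn (1.07), Nanog (0.41), Klf4 (−0.42), Lin28b (−0.42), Tfe3 (0.30), Sqstm1 (0.20), Sesn2 (1.43), Mki67 (−0.37), Ccnd1 (−0.64), Txnip (−0.36), Ddit4 (1.58) and Mtor (−0.36).

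A library lay far from the others of its group in 4 of 116 groups of 4 libraries, where chance gives about 1 in 20. The gap to the nearest library, divided by the range of the group, was above the critical value for 4 libraries for Lin28b in KO paused replicate 2 (0.858), for genes detected in wild-type normal replicate 4 (0.886, 23394 genes) and wild-type paused replicate 2 (0.865, 23770 genes), and for the share of the 10 most abundant genes in wild-type paused replicate 2 (0.906).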

How the results depend on the processing

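The term for replicates 1 and 2 against 3 and 4, these replicates alone, the fits without Gm19220 and without the shifted regions, and site effects in genes with a mean log2 CPM of at least 3 were chosen only after the data were seen. The other alternatives were planned.

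The first ranges exclude the setting with a change of at least 1 on the log2 scale and the fits without 1 library, given after them. Over the other alternatives chosen beforehand, called genes numbered 10190 to 11611 for pausing in wild-type cells and 10803 to 12832 in KO cells. They numbered 7075 to 8179 for the interaction, 10727 to 13315 for Dgcr8 loss in normal and 10359 to 12703 in paused culture. Over these same alternatives the share of higher or positive genes was 49.99% to 55.4% and 49.5% to 51.5% for pausing. It was 38.9% to 45.5% for the interaction, and 47.8% to 50.4% and 46.4% to 49.9% for Dgcr8 loss. With a change of at least 1 on the log2 scale the counts were 1953, 2901, 1659, 4038 and 3462, since that setting keeps only larger changes. Leaving out 1 library gave 10917 to 11329, 12117 to 12353, 7234 to 8261, 12364 to 12783 and 11772 to 12103 genes. Scaling moved the median of all genes by at most 0.029.

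Same-numbered libraries deviated together at most weakly (r across genes from −0.049 to 0.097, 7 of 16 libraries closest to their own number). Between the wild-type cultures, r was positive for libraries on the same side of the replicate split reported above (0.013 to 0.080). It was negative for libraries on different sides (−0.011 to −0.081). Between the KO cultures, same-numbered libraries had r from −0.049 to 0.059. These values do not decide whether the numbers mark a shared batch. With the replicate number as a block, 11601, 12780, 8088, 13013 and 12440 genes and 57 list shifts were called. The block ended the call of p53 targets on pausing of KO cells. It added those of germline genes for the interaction and of neuroectoderm markers for Dgcr8 loss in paused cells.

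The correlation of the pausing response between genotypes was 0.657 (Spearman 0.665) with the strict filter, which drops low genes, and 0.527 to 0.578 (Spearman 0.556 to 0.597) when 1 replicate number was left out. The size of the KO relative to the wild-type response ranged from 0.763 to 0.833 with 1 replicate left out, and that of the wild-type relative to the KO response from 0.582 to 0.60, and was 0.632 with the strict filter. Of 56 list shifts 5 were called with an estimated correlation, which allows for genes of a list that vary together, and 134 with fry, which tests a list against no change.

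Sites AGCACTT had an effect of 0.0612 in normal and 0.0545 in paused culture with the 6-base core, and 0.112 and 0.156 without covariates. Under both settings they passed the test, unlike in the reported model (adjusted p = 0.0069 and 0.026 with the core, 1.4e-06 and 2.1e-10 without covariates). They did not pass with the 3′ UTR of the most abundant transcript (adjusted p = 0.37 and 0.21) or in genes with a mean log2 CPM of at least 3 (0.54 and 0.40). Without covariates the calls of TACTTGA (−0.0050) and ATAAGCT (−0.016) in normal culture were lost, and the latter also with the 3′ UTR of the most abundant transcript (adjusted p = 0.079). Without covariates the effects of AGCACTT on pausing of wild-type cells (0.0601) and of TGTTTAC on Dgcr8 loss in normal culture (0.0285) reversed, and with length-scaled TPM counts so did the effect of Dgcr8 loss on Mtor in normal culture (−0.058). The cause was not tested.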

Other observations

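The comparison of replicate pairs in this part was chosen only after the data were seen. Further named genes rose on pausing. In wild-type cells the peptide-processing enzyme Cpe rose by 2.26, the cortical transcription factor Cux2 by 2.16 and the kinase Mapk4 by 2.19. In KO cells the adhesion receptor Adgrg1 rose by 2.13 and the splicing regulator Nova2, known from neurons, by 2.30.

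Across genes, which are not independent replicates, fold changes in replicates 1 and 2 and in replicates 3 and 4 correlated with r = 0.706 for pausing in wild-type cells, 0.763 in KO cells, 0.492 for the interaction, and 0.861 and 0.909 for Dgcr8 loss in normal and paused culture. Of the 8677 genes called in both pairs for pausing in wild-type cells, 263 had opposite signs.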
